A study of Caenorhabditis elegans with 2 samples.

How the data were processed

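ChIP-seq peak lists were analysed for 2 biological replicates of L2 larvae of strain OP90, which expresses eGFP-tagged NHR-6 from an integrated transgene, and for both replicates pooled. Per the labels, whole animals of pooled sex were used and the precipitated protein was eGFP-NHR-6. Replicate numbers were taken from the labels, and both samples formed 1 group. The labels name a possible control experiment, which was not analysed here, and they give no extraction protocol.

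Per the file list that comes with each sample, the authors made a relaxed list (peaks and background) from each replicate's alignment and 1 further file that the list does not describe. Another relaxed list was made by the authors from both alignments together. The optimal set was derived by the authors from the pooled and both replicates' relaxed lists with the irreproducible discovery rate (IDR), a measure of how consistently peaks rank in replicates. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each deposited list holds 1 signal value per peak, the authors' own, whose scaling is not given in the sources used here. It was used only to describe, rank and filter peaks within a list. The deposited lists also give −log10 of the q-value and the summit's offset from the peak start. Peaks of replicate 1 were 340 bp wide, those of replicate 2 were 364 bp and pooled ones 344 bp in nearly all cases, with the summit in the middle. Of the optimal peaks 93.5% had the pooled width, and the summit of others can lie off the middle. How far a summit lies from the bound site was not measured. Read depth per sample is unknown, and no interval that needs it is given. Exact intervals on shares of peaks or genes (Clopper-Pearson, 95%) cover counting error only.

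Lists on ce11 were used, since this build equals the reference WBcel235, and gene models were taken from Ensembl release 115. Lists on ce10 served as an alternative, with no coordinates converted. All 1662 optimal peaks were the 1662 highest of the pooled relaxed list (1609 of 1609 on ce10), so taking the highest pooled peaks without the IDR filter gave the same set.

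Summits of both replicates within 100 bp were called shared. Overlap and promoter share were tested with 10000 circular rotations of the summits along each chromosome, one-sided. A gene was called bound where an optimal summit lay from 1000 bp upstream to 200 bp downstream of an annotated 5′ end, and a summit could bind several genes. Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment at 0.05 compared 30 gene lists with the remaining protein-coding genes. It also compared 9 classes of non-coding gene having at least 50 members with protein-coding genes, and X with autosomes. List membership went by symbol, and every gene that shares a symbol was counted. This counting was set after first results had been seen, which had taken 1 gene per symbol. It raised the histone list from 50 to 72 genes and moved it from past to not past the threshold, and the lists past the threshold went from 13 to 12. Of the listed symbols 9 were not found among protein-coding genes, 5 of them microRNA genes of the heterochronic list. Sequence windows of 101 bp at the summit were compared with windows centred 250 bp to the right by the exact McNemar (binomial) test, for the NR4A element AAAGGTCA and for every 8-mer in at least 10 windows. Bound genes are neighbours of summits, and no effect on expression was measured. P-values over peaks or genes describe these 2 samples.

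The lists, tests, alternatives and the rule for named items were fixed before the data were examined, except for the counting of shared symbols and where a test is said to be chosen later. Named items were the 20 highest optimal peaks, up to 4 bound members of each list by signal, nhr-6 and unc-119, the 5 top 8-mers by p, and every list past the threshold. Alternatives were the upper part of the optimal set (831 peaks), each replicate left out in turn, the other build, other overlap distances, promoter windows, gene assignments, backgrounds, flanks, sequence windows and forms of the element, rotation in place of Fisher's exact test (1000 rotations, two-sided), and removal of peaks at the transgene loci.

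The procedures were tested on 20 simulated sets of 1662 peaks. Random sets gave 0 significant promoter shares, overlaps or lists. A planted list of 60 genes with 15 bound was called in 20 of 20 sets, and a planted overlap of 50% was measured as 50.2% on average. In 5 further simulations an 8-mer planted in 5% of windows came first each time, and 0 8-mers were called without planting. Random summits were drawn evenly along the chromosomes, and the simulations used fewer rotations than the data. Their summit and flank windows were thus alike in base composition, unlike the real ones (44.7% and 35.4% G and C). The check without planting therefore cannot show how many real 8-mer calls come from base composition. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.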

Results

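Binding of NHR-6 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole second-stage (L2) larvae of Caenorhabditis elegans. NHR-6 is the worm member of the NR4A group of nuclear receptors, a group of DNA-binding transcription factors. The strain, OP90, carries an integrated transgene that expresses the receptor fused to the green fluorescent protein eGFP. Its background is mutant in unc-119, a gene needed for movement that worm transgenes often carry as a rescue marker. Animals of both sexes were pooled, and 2 biological replicates formed a single group. The labels name no second condition, so the comparisons were between the replicates, between bound and other genes, and between peak summits and nearby sequence. No input or untagged sample was analysed here. Read depth is unknown from peak lists. Each relaxed list held 30000 peaks, weak candidates included, and the set that passed the authors' reproducibility filter (the optimal set) held 1662 peaks on genome build ce11 and 1609 on ce10. All positions are on ce11.

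Of the 20 highest peaks, 11 were in promoter windows, 10 of these on autosomes, and 9 were outside promoter windows, all on the X chromosome. The highest peak (II, 10563451 to 10563687) lay 163 bp upstream of cdc-48.1, which encodes an ATPase of protein quality control. Its signal was 912.7 in the pooled list, 627.8 in replicate 1 and 305.2 in replicate 2. Peaks at the ribosomal protein genes rpl-3 (III, 3867455 to 3867694, signal 787.6), rpl-20 (IV, 4749940 to 4750198, signal 726.4), rpl-15 (IV, 654805 to 655044, signal 587.4) and rpl-35 (III, 7854581 to 7854820, signal 570.6) ranked 2, 3, 6 and 7. The rpl-20 window was shared with Y17G9B.5 and the rpl-15 window with K11H12.8. The remaining promoter peaks in the 20 were at enee-1 (signal 535.2), nspc-17 (455.7, the only promoter peak on X), rps-1 with ifet-1 (454.1), the histone gene his-37 (451.7), tasp-1 with K01G5.10 (450.6), and iff-2 with F54C9.14 (411.0). rps-1 encodes a ribosomal protein and iff-2 the translation factor eIF5A.

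The highest X-linked peak (X, 8036291 to 8036633, signal 720.1) was intergenic, 4881 bp upstream of xol-1, the switch gene of sex determination and dosage compensation. Intergenic X peaks followed at 13700675 to 13701060 (signal 609.6, nearest gene K02D3.1), 9465707 to 9466025 (559.7, ZK899.6), 11094005 to 11094364 (554.5, W02H3.3), 11937397 to 11937674 (536.7, F55G7.5), 16681999 to 16682235 (512.3, F22H10.2) and 12363090 to 12363338 (406.1, F19H6.5). Introns held the peaks at 2996936 to 2997281 (signal 533.4, within Y41G9A.17) and 6296360 to 6296755 (444.9, within mom-1, a gene of Wnt ligand secretion). All 20 peaks were among the 1662 highest of each replicate, at rank 28 or better in replicate 1 and rank 35 or better in replicate 2.

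The replicates shared many more sites than chance placement gives, but they did not contribute equally to the optimal set. Of the 1662 highest peaks of replicate 1, 818 (49.2%, 95% exact interval 46.8 to 51.7%) had a summit within 100 bp of a summit among the 1662 highest of replicate 2. Rotated summits gave 0.350% on average and at most 1.38% (one-sided rotation permutation test, p = 0.0001, the smallest possible with 10000 rotations). Across the 818 matched peaks the signals ranked alike with a Spearman rho of 0.58, a description only, since peaks are not independent replicates. Among the optimal peaks, 1419 (85.4%) were in the 1662 highest of replicate 1 and 998 (60.05%) in those of replicate 2, and 837 were in both. The relaxed list of replicate 1 held 1640 of them (98.7%) and that of replicate 2 held 1426 (85.8%). Signals ran from 11.2 to 627.8 (median 15.4) in replicate 1 and from 5.31 to 305.2 (median 7.67) in replicate 2, and levels were not compared between them. Peaks with a q-value of 0.01 or less numbered 3180 in replicate 1 and 2487 in replicate 2.

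**Figure D1:**
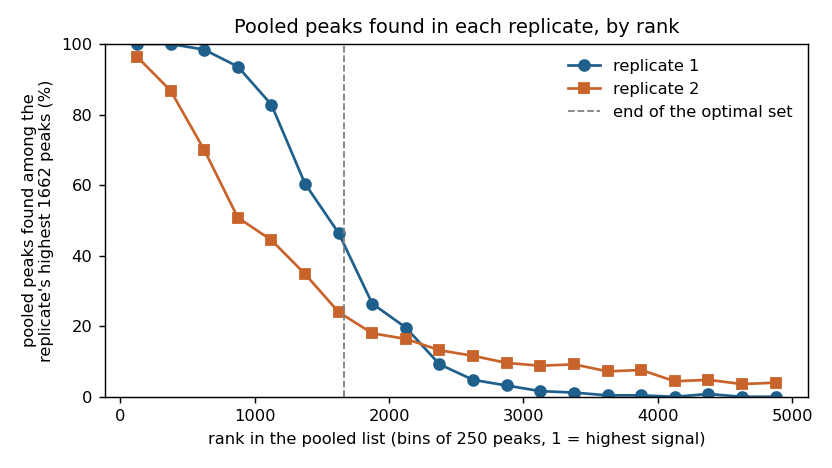
Share of pooled peaks found among each replicate's 1662 highest peaks (vertical axis, percent) by rank in the pooled list (horizontal axis, bins of 250 peaks), with circles for replicate 1, squares for replicate 2 and a dashed line at the end of the optimal set. Of the first 250 peaks, all were found in replicate 1 and 96.4% in replicate 2, and in ranks 1001 to 1250 the shares were 82.8% and 44.4%.

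Binding was concentrated at promoters. Of the 1662 optimal summits, 928 (55.8%, 95% exact interval 53.4 to 58.2%) lay from 1000 bp upstream to 200 bp downstream of an annotated 5′ end of a protein-coding transcript. Rotated summits gave 25.6% on average and at most 32.9% (one-sided rotation permutation test, p = 0.0001, the smallest possible). The median distance from a summit to the nearest 5′ end was 585 bp, and 281 summits lay in the windows of more than 1 gene. Of the remaining 734 summits (44.2%), 396 were intergenic, 234 were in introns, 54 in non-coding genes, 29 in coding exons, 13 in 3′ UTRs and 8 in 5′ UTRs. Coding exons held 1.74% of the summits against 18.9% of rotated ones, introns 14.1% against 27.5%, and intergenic sequence 23.8% against 22.04%; these shares by class were not tested. In all, 1186 of 19973 protein-coding genes (5.94%) had a summit in the promoter window and are called bound here. Annotated 5′ ends of worm genes often mark a splice leader site and not the start of transcription, which limits what the window captures.

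Genes of protein synthesis and energy metabolism were bound far more often than other genes. Of 30 gene lists fixed before the data were examined, 12 differed from the remaining protein-coding genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjustment over the 30 lists), 8 with a higher and 4 with a lower bound share. For every list, signal that any tagged protein gives at active promoters stays open, since no input or untagged sample was analysed here. Ribosomal protein genes had 45 of 81 bound (55.6%, 95% exact interval 44.1 to 66.6%) against 5.74% of other genes (odds ratio 20.5, exact adjusted p = 1.4e-32). Besides the 4 rpl genes named above, these included genes of both ribosomal subunits. The ribosomal share was the highest of the 30 lists, but giving each summit only to its nearest 5′ end lowered it to 35.8% (exact adjusted p = 6.0e-18), below the heterochronic (36.4%) and bZIP lists. The heterochronic share was also the higher with the window from 2000 bp upstream (63.6% against 55.6%), among the 831 highest peaks (45.5% against 41.98%) and among genes with a relaxed peak in both replicates (71.4% against 69.8%). Nuclear genes of the respiratory chain had 21 of 51 bound (41.2%, odds ratio 11.3, exact adjusted p = 3.1e-12), among them the cytochrome c oxidase genes cox-5A (III, summit 12905178, signal 403.3), cox-5B (226.0) and cox-6B (210.5) and the ATP synthase gene atp-1 (196.7). Translation factors and tRNA synthetases had 15 of 61 bound (24.6%, odds ratio 5.22, exact adjusted p = 9.8e-06). The elongation factor genes eef-1A.1 (signal 287.9), eef-2 (257.6) and eef-1G (228.1) came after iff-2. Among genes with a relaxed peak in both replicates as background, the translation list missed the threshold (exact adjusted p = 0.0527).

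Protein folding and turnover genes formed another bound group. Heat shock proteins and chaperones had 18 of 68 bound (26.5%, odds ratio 5.78, exact adjusted p = 4.1e-07), with the highest signals at the chaperonin genes cct-1 (284.3) and cct-8 (221.1) and the Hsp70-family genes hsp-110 (282.9) and hsp-1 (192.9). With the nearest 5′ end only, 8 of the 68 were bound (11.8%, odds ratio 2.87, exact adjusted p = 0.0310). Proteasome genes had 7 of 33 bound (21.2%, odds ratio 4.28, exact adjusted p = 0.00839), led by rpn-3 (282.9), rpt-2 (133.2), pas-4 (108.1) and pas-5 (82.3). The rpn-3 and hsp-110 windows shared 1 summit (III, 8447152). The proteasome call was lost among the 831 highest peaks (exact adjusted p = 0.0765) and against genes with a relaxed peak in both replicates (exact adjusted p = 0.763).

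The lists of bZIP factors, heterochronic genes and cell cycle genes were also bound more often. Of the bZIP transcription factor genes, 10 of 25 were bound (95% exact interval 21.1 to 61.3%, odds ratio 10.6, exact adjusted p = 4.5e-06), led by cebp-1 (X, summit 1454637, signal 118.3), the AP-1 gene jun-1 (II, summit 9113026, signal 117.0), the oxidative stress regulator skn-1 (IV, summit 5656120, signal 111.0) and the CREB gene crh-1 (III, summit 11657362, signal 102.9). Without replicate 1, 7 of the 25 were bound (odds ratio 6.17, exact adjusted p = 0.00183). Heterochronic genes, which time larval cell fates, had 5 of 11 bound (45.5%, 95% exact interval 16.7 to 76.6%, odds ratio 13.3, exact adjusted p = 0.000938), and 27.3% with the promoter window from 500 bp upstream (exact adjusted p = 0.0345). Their highest peaks were at nhl-2 (297.6) and ain-1 (259.4), cofactors of microRNA silencing, and at lin-28 (157.8) and lin-66 (100.8). Cell cycle genes had 7 of 33 bound (21.2%, odds ratio 4.28, exact adjusted p = 0.00839), including cdc-14 (146.2), pcn-1, which encodes the replication clamp PCNA (125.4), the E2F gene efl-1 (112.5) and the cyclin gene cyb-1 (99.7). Without replicate 1 the cell cycle share was 12.1% (exact adjusted p = 0.234), and it also missed the threshold against genes with a relaxed peak in both replicates (exact adjusted p = 0.212).

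The chemoreceptor, F-box, collagen and major sperm protein (below, sperm) lists were bound less often, though all but the first lost this call in several settings. Chemoreceptor genes, which act in few sensory neurons, had 4 of 1364 bound (0.293% against 6.35% of other genes, exact adjusted p = 2.0e-30), namely sri-5 (signal 83.4), srh-2 (75.9), srdh-1 (58.8) and srh-269 (56.4). F-box genes had 5 of 322 bound (1.55%, exact adjusted p = 0.000796), with the highest signals at fbxb-58 (241.1), fbxb-85 (158.3), fbxc-54 (149.0) and fbxa-90 (112.5). The fbxa-90 summit was the one named above for efl-1. Collagen genes had 2 of 156 bound (1.28%, exact adjusted p = 0.0244), col-38 (99.5) and col-71 (73.6), or 1 with either replicate left out (exact adjusted p = 0.00573 and 0.00674). The col-38 summit was also in the window of the ribosomal protein gene rpl-5. Major sperm protein genes had 0 of 85 bound (95% exact upper limit 4.25%, exact adjusted p = 0.0244). With rotated summits in place of Fisher's exact test, which do not stay at promoters, the chemoreceptor list kept its call and the F-box (permutation adjusted p = 1.0), collagen (1.0) and sperm lists (0.688) lost theirs. Against genes with a relaxed peak in both replicates, these 3 lists also missed the threshold (exact adjusted p = 0.849 for F-box, 0.190 for collagen and 0.275 for major sperm protein genes). Among the 831 highest peaks they missed it as well (exact adjusted p = 0.145, 0.117 and 0.263). The collagen and sperm calls were lost with the window from 500 bp upstream (exact adjusted p = 0.0771 each). The sperm call was also lost with the window from 2000 bp upstream (exact adjusted p = 0.251), with the nearest 5′ end only (exact adjusted p = 0.0782) and without replicate 2 (1.18%, exact adjusted p = 0.175).

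**Figure D2:**
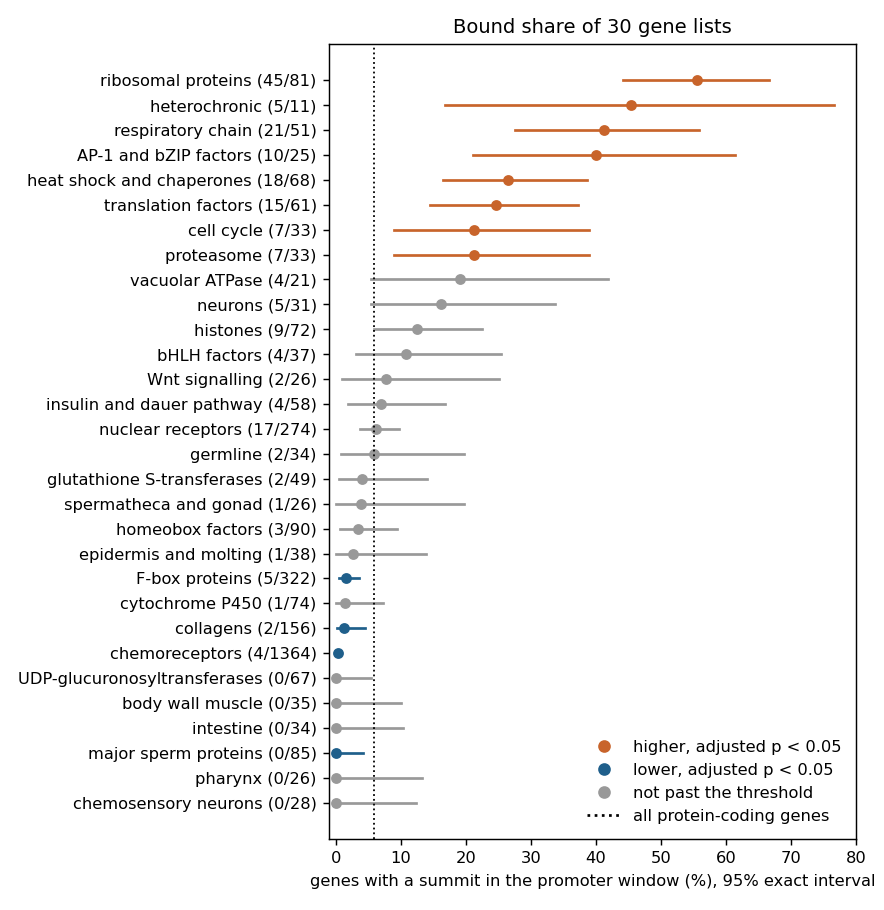
Share of the genes of each of the 30 lists with an optimal-set summit in the promoter window (horizontal axis, percent; points with 95% exact intervals; bound and total genes beside each name), with the 5.94% of all protein-coding genes as a dotted line. Ribosomal protein genes stand at 55.6% and chemoreceptor genes at 0.293%.

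The other 18 lists did not pass the adjusted threshold. Nuclear receptor genes, the family of NHR-6, had 17 of 274 bound (6.20%, exact adjusted p = 0.885), with the highest signals at nhr-49 (145.5), a regulator of fat metabolism, and at nhr-40 (109.1), nhr-1 (107.6) and nhr-68 (98.9). Spermatheca and gonad genes, listed because nhr-6 is needed for spermatheca development, had 1 of 26 bound (3.85%, exact adjusted p = 1.0), the cell junction gene ajm-1 (88.4), and 2 without replicate 1, a share then above that of other genes (7.69%, exact adjusted p = 0.769). The ajm-1 summit (X, 9091561) also lay in the windows of tRNA genes, 67 bp downstream of the nearest tRNA 5′ end. Neuronal genes had 5 of 31 bound (16.1%, exact adjusted p = 0.0687), including rab-3 (122.8), maco-1 (87.9), unc-18 (70.6) and egl-21 (66.6). Vacuolar ATPase genes had 4 of 21 bound (19.05%, exact adjusted p = 0.0687), vha-8 (149.4), vha-12 (98.6), vha-15 (79.6) and vha-1 (68.5). Histone genes had 9 of 72 bound (12.5%, exact adjusted p = 0.0718). The histone list passed without replicate 2 (18.1%, exact adjusted p = 0.00075), among the 831 highest peaks (exact adjusted p = 0.0387), with the windows from 500 bp (exact adjusted p = 0.0186) and 2000 bp upstream (exact adjusted p = 0.0266) and against genes with a relaxed peak in both replicates (exact adjusted p = 0.00751). Neuronal genes passed with the window from 2000 bp upstream (exact adjusted p = 0.00771) and with the nearest 5′ end only (exact adjusted p = 0.0310), and vacuolar ATPase genes with the windows from 500 bp (exact adjusted p = 0.0375) and 2000 bp upstream (exact adjusted p = 0.0129). With rotated summits the histone, nuclear receptor (permutation adjusted p = 0.00545 each), neuronal (0.0138) and vacuolar ATPase lists (0.00999) passed too. When the bound state was shifted along the gene order, a test chosen after the values were seen that keeps summits at promoters, the nuclear receptors did not pass (17 bound against 12.2 on average, one-sided permutation p = 0.130). Besides his-37, the histone peaks with the highest signals were those shared by his-67 and his-68 (140.6) and by his-31 and his-32 (116.4). Fisher's exact test counts genes that share a summit as independent. Its p-values for the histones, and for other lists with such neighbours, can therefore be too small.

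The bHLH factor genes had 4 of 37 bound (10.8%, exact adjusted p = 0.418), hlh-11 (135.0), aha-1 (96.9), hlh-30 (78.1) and the hypoxia factor hif-1 (71.8). Homeobox genes had 3 of 90 (3.33%, exact adjusted p = 0.535), ceh-38 (201.4), ceh-20 (93.0) and unc-42 (53.0), and 2 without replicate 1. The unc-42 peak was below the 1662 highest of both replicates (rank 2152 in replicate 1 and 1954 in replicate 2). Insulin and dauer pathway genes had 4 of 58 (6.90%, exact adjusted p = 0.885), ins-39 (271.8), akt-2 (95.6), din-1 (86.4) and the FOXO gene daf-16 (60.4). Wnt genes had 2 of 26 (7.69%, exact adjusted p = 0.832), mig-5 (284.3, the summit also in the cct-1 window) and dsh-2 (73.0). Germline genes had 2 of 34 (5.88%, exact adjusted p = 1.0), cgh-1 (65.7) and gld-2 (62.7), and none without replicate 1. Glutathione S-transferase genes had 2 of 49 (4.08%, exact adjusted p = 1.0), gst-9 (55.05) and gst-43 (53.4), and none without replicate 2. Cytochrome P450 genes had 1 of 74 (1.35%, exact adjusted p = 0.234), cyp-13A2 (59.6), and epidermis and molting genes 1 of 38 (2.63%, exact adjusted p = 0.871), sqt-2 (67.2). With either replicate left out 3 of the 38 were bound (7.89%), a share above that of other genes (exact adjusted p = 0.617 without replicate 1 and 0.569 without replicate 2). None were bound of 67 UDP-glucuronosyltransferase genes (exact adjusted p = 0.0687, and 0.0239 with the window from 2000 bp upstream, again with none bound), 35 body wall muscle genes (exact adjusted p = 0.418), 34 intestinal genes (exact adjusted p = 0.418), 28 chemosensory neuron genes (exact adjusted p = 0.535) or 26 pharyngeal genes (exact adjusted p = 0.535), though 1 intestinal and 1 pharyngeal gene were bound without replicate 1. Of the named list members, vha-12, cgh-1, din-1 and cyp-13A2 had no matching summit within 100 bp in the relaxed list of replicate 2. Whole larvae were used, so a list of cell type markers groups target genes and names no cells.

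Of the classes of non-coding genes, 4 were bound more often than protein-coding genes and 3 less often, and 3 of the 4 lost this call without replicate 1. Small nucleolar RNA (snoRNA) genes had 65 of 346 bound (18.8%, 95% exact interval 14.8 to 23.3%) against 5.94% of protein-coding genes (odds ratio 3.66, exact adjusted p = 1.4e-15). Small nuclear RNA (snRNA) genes had 14 of 129 (10.9%, exact adjusted p = 0.0473), microRNA genes 26 of 261 (9.96%, exact adjusted p = 0.0211) and tRNA genes 51 of 612 (8.33%, exact adjusted p = 0.0289). Genes of SL2 splice leader RNAs, 6 of 18 bound (33.3%), were among the 14, and the snRNA class was not tested without them. Lower shares were found for other non-coding RNA genes (369 of 7764, 4.75%, exact adjusted p = 0.000219), piRNA genes (136 of 15363, 0.885%, exact adjusted p = 1.2e-158) and pseudogenes (12 of 2128, 0.564%, exact adjusted p = 4.8e-37). Long intergenic RNA genes (18 of 194, 9.28%, exact adjusted p = 0.0732) and antisense RNA genes (3 of 100, 3.00%, exact adjusted p = 0.287, and 5 without replicate 2) did not pass. Without replicate 1 the microRNA (6.90%), snRNA (10.9%) and tRNA (5.72%) calls were lost (exact adjusted p = 0.573, 0.0667 and 0.863), the tRNA share then lying below the 5.96% of protein-coding genes. The lower share of other non-coding RNA genes was lost without replicate 2 (exact adjusted p = 0.0516), and the snRNA (exact adjusted p = 0.133) and tRNA (exact adjusted p = 0.641) calls were lost among the 831 highest peaks. With the window from 500 bp upstream the microRNA (5.36%, exact adjusted p = 0.555) and snRNA (8.53%, exact adjusted p = 0.0828) calls were lost, and with that from 2000 bp the snRNA (10.9%, exact adjusted p = 0.280) and tRNA (9.97%, exact adjusted p = 0.104) calls. Long intergenic RNA genes passed without replicate 2 (10.3%, exact adjusted p = 0.0147). Only 27 of the 65 bound snoRNA genes had a summit outside protein-coding promoters, since many lie within or beside other genes. Fisher's exact test counts genes as independent, but neighbouring genes of a class can share a summit. A single summit (III, 2172122) lay in the windows of mir-64, mir-65, mir-66 and mir-229. The p-values of these classes can therefore be too small, and no rotation was run for them.

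The canonical NR4A element was rare at the summits. AAAGGTCA, on either strand, occurred within 50 bp of 8 of 1662 summits (0.481%, 95% exact interval 0.208 to 0.946%) and in 11 equal windows centred 250 bp to the right (0.662%, exact McNemar test, two-sided, p = 0.648). The share was 0.301% without replicate 1 (exact p = 0.581) and 0.602% without replicate 2 (exact p = 0.629). The shorter forms AAGGTCA (1.08% against 0.963%, exact p = 0.864) and AGGTCA (2.89% against 2.05%, exact p = 0.146) also did not differ detectably. Of the 415 highest peaks 2 had the full element and of the 415 lowest 1 had it (Fisher's exact test, two-sided, p = 1.0). Against shuffled summit sequence with the same dinucleotides (0.0602%) the share was higher (exact p = 0.0391), whereas against the left flank (0.361%) it did not differ detectably (exact p = 0.791).

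Other sequences were frequent at the summits. Of 9843 8-mers tested with reverse complements merged, 1145 differed between summit and right flank (exact McNemar test, Benjamini-Hochberg adjustment), 568 more frequent at the summit and 577 in the flank. Without replicate 1 the count was 311, 220 of them more frequent at the summit. AGACGCAG was in 178 summit windows (10.7%) and 12 flank windows (0.722%, exact adjusted p = 1.0e-35). The overlapping 8-mers GACGCAGA (151 against 6 windows), GAGACGCA (161 against 9) and AGAGACGC (121 against 4) came next, and TTTAAAAA was less frequent at summits (18 against 139 windows, and 53 against 120 without replicate 1). The windows differed in base composition, with 44.7% G and C at summits and 35.4% in the flank. TTTAAAAA did not differ from shuffled summit sequence (18 against 22 windows, exact adjusted p = 1.0), an alternative chosen after seeing the data, whereas the other 4 named 8-mers did. GAGAGAGA, named after its values were seen, was in 161 summit and 30 flank windows (exact adjusted p = 8.8e-22).

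**Figure D3:**
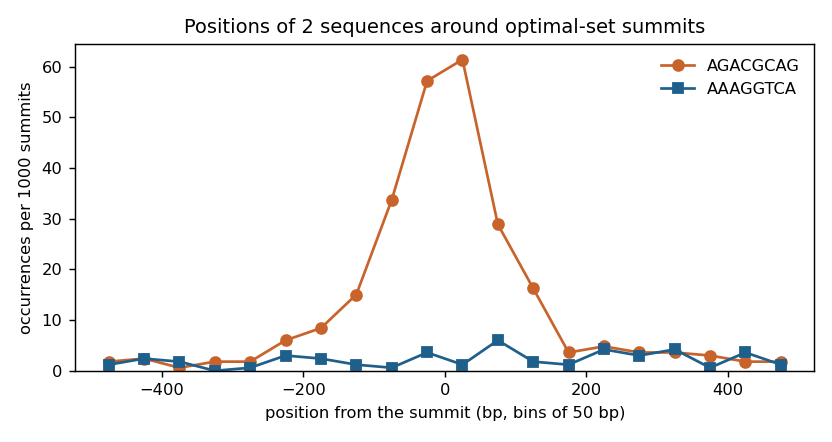
Occurrences per 1000 optimal-set summits (vertical axis) of AGACGCAG and AAAGGTCA on either strand, in bins of 50 bp from 500 bp left to 500 bp right of the summit (horizontal axis). AGACGCAG reaches 61.4 per 1000 summits in the bin from 0 to 50 bp, and AAAGGTCA stays at 6.02 or below in every bin.

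Whether genes on X differed detectably from autosomal genes in how often they were bound depended on the setting. On X 183 of 2731 protein-coding genes were bound (6.70%, 95% exact interval 5.79 to 7.70%) and on autosomes 1003 of 17242 (5.82%, odds ratio 1.16, Fisher's exact test, two-sided, p = 0.0739). The direction turned without replicate 1 (5.16% against 6.08%, exact p = 0.0613), and the difference passed the threshold without replicate 2 (6.52% against 5.53%, exact p = 0.0403). It also passed with the window from 2000 bp upstream (8.93% against 7.77%, exact p = 0.0394) and, more widely, with the nearest 5′ end only (6.11% against 4.205%, exact p = 1.7e-05). Peaks lay outside promoter windows more often on X, a comparison chosen after the values were seen. Of the X peaks 199 of 370 (53.8%) were outside promoter windows, against 535 of 1292 (41.4%) on autosomes (odds ratio 1.65, Fisher's exact test, two-sided, p = 3.1e-05). Single autosomes ranged from 35.4% (I) to 48.2% (IV). X held 2731 of 19973 protein-coding genes on 17.7% of the genome length, so fewer for its length than autosomes. No share expected from promoter coverage was computed for each chromosome, so the difference need not reflect another placement of peaks. X held 36.4% of the peaks outside promoters among the 415 highest peaks, 22.5% and 21.3% in the next groups of 415 and 29.8% among the 417 lowest.

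**Figure D4:**
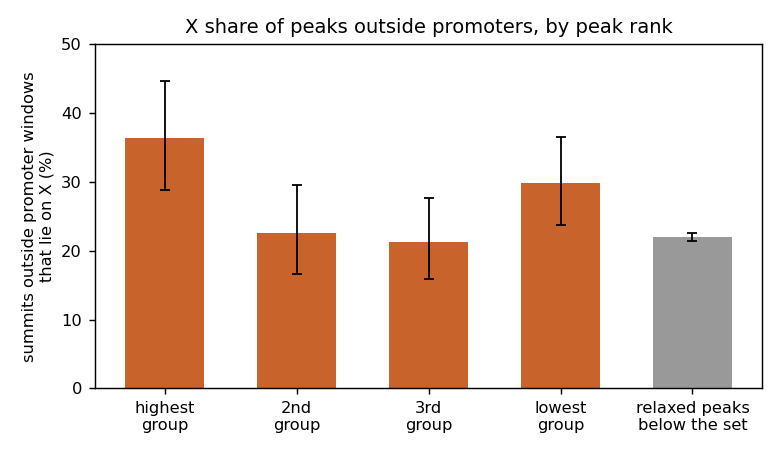
Share of summits outside promoter windows that lie on X (vertical axis, percent, with 95% exact intervals) in groups of 415 peaks of the optimal set (417 in the last), from the highest to the lowest signal, and among relaxed pooled peaks below the optimal set. The share is 36.4% in the highest group and 21.9% among the relaxed peaks.

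Chromosome V had the fewest optimal peaks per length, 9.56 per Mb, against 21.1 on chromosome III and 20.9 on X. Part of this came from stretches longer than 50 kb without a summit in any of the 3 relaxed lists, examined after the values were seen. There were 8 such stretches, 5 of them on V, with a total of 3.89 Mb and 986 protein-coding genes (4.94%), so genes there could not be called bound. The longest ran from 11929185 to 14800270 on V and held 718 protein-coding genes. Outside the stretches V had 11.6 peaks per Mb. The stretches held 123 chemoreceptor genes, and without the genes in them the chemoreceptor share was 0.322% (exact adjusted p = 7.3e-29).

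**Figure D5:**
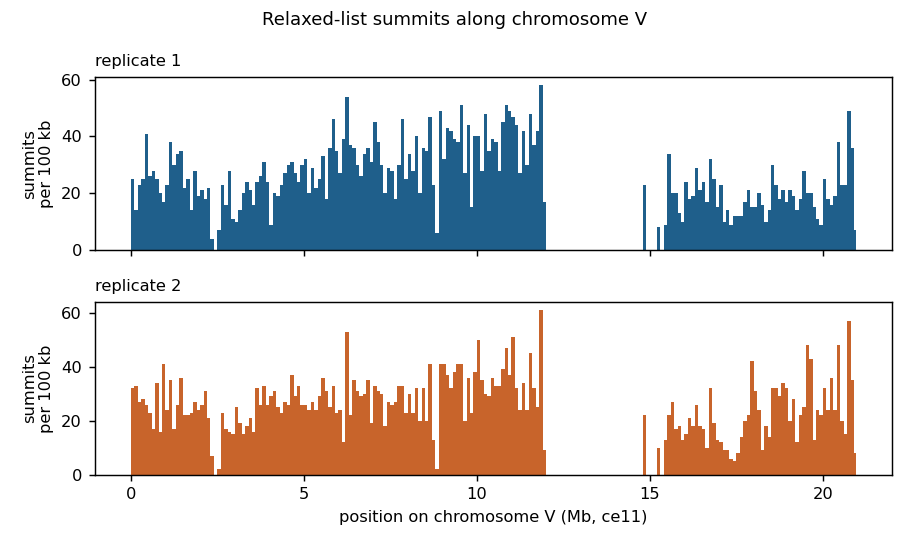
Relaxed-list summits per 100 kb (vertical axes) along chromosome V (horizontal axis, Mb, ce11) in replicate 1 and replicate 2. Both lists are empty from 11929185 to 14800270, the longest stretch without a summit.

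The nhr-6 and unc-119 loci were read apart, since the transgene may bring extra copies of them. Copy number was not measured. Around nhr-6 (III, 3573581 to 3578771) neither the optimal nor the relaxed pooled list had a peak within 20 kb, where the median protein-coding gene had 0.289 relaxed peaks per kb. The gene lay in a stretch without a summit in any relaxed list (III, 3554140 to 3610082). Whether NHR-6 does not bind at its own gene or its signal is missing there for another reason cannot be told from the lists. Around unc-119 (III, 10902641 to 10908935) there were 2 optimal and 15 relaxed peaks within 20 kb, the highest with signal 73.1 (rank 912). The unc-119 promoter window held a relaxed peak with signal 25.5 (rank 7449), below the optimal set, and unc-119 was not called bound.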

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

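The shuffle for 8-mers, the wider window, the restriction to summits outside promoters, the X share with the 415 highest peaks, the removal of genes in stretches without a summit and the counting of 1 gene per shared symbol were chosen after seeing the data. Unknown read depth and 2 replicates limit all settings, and causes were not tested unless given. Replicate overlap (37.1 to 57.0%), and promoter share (45.6 to 69.4%), kept their direction and side of the threshold in every setting run. The rank correlation was 0.46 over optimal peaks found in both relaxed lists. The share of the NR4A element did not differ detectably from any flank run, though its sign varied. Against the dinucleotide shuffle the difference had the opposite sign and passed the threshold (0.481% against 0.0602%, exact p = 0.0391). In windows of the usual peak width it was 1.62% against 1.87% (exact p = 0.636), and outside promoters 0.409% against 0.817% (exact p = 0.508).

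The count of 8-mers past the threshold was 1145. It was 694 with the 831 highest peaks, where 3510 were tested, 307 against the shuffle (278 of them higher at summits) and 311 to 1329 with a replicate left out, the lower without replicate 1. Gene lists past the threshold numbered 12 (8 higher). There were 7 (6 higher) against genes with a relaxed peak in both replicates, a smaller background, and 6 of these were among the 12. Rotation, which does not keep summits at promoters, gave 13 (12 higher), 9 of them among the 12. For single lists, non-coding classes, 8-mers and counts of named items, the planned settings left 347 values on the same side of the threshold (77 of these could not change, since the setting left the peaks or bound genes as they were), 28 no longer passed, 15 newly passed, and 1, the tRNA share without replicate 1, no longer passed and changed direction. The histones also passed with 1 gene per shared symbol (50 genes, exact adjusted p = 0.00763) and without genes in the stretches (15.8%, exact adjusted p = 0.0210), with 13 lists past the threshold in each case. Of the 78 named list members, 61 to 73 stayed bound with a replicate left out.

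The X share of bound genes was 5.16 to 6.52% with a replicate left out, 8.93% with the window from 2000 bp upstream (7.77% on autosomes, exact p = 0.0394) and 6.11% with the nearest 5′ end only (4.205%, exact p = 1.7e-05). With the 415 highest peaks it was 1.68% against 1.93% on autosomes (exact p = 0.407), and without genes in the stretches 6.70% against 6.17% (exact p = 0.286). Non-coding classes past the threshold numbered 4 to 7 with a replicate left out. The tRNA share was 5.72 to 9.31%, and the lower, without replicate 1, lay on the other side of that of protein-coding genes (5.96%).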

Other observations

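The comparisons of tRNA genes, of splice leader genes and of 8-mers between classes of peaks were chosen after the results were seen, as were the shift of bound genes along the gene order and the count of empty bins. The other tests were set before their results were seen.

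Bound tRNA genes lay mostly on X. On X 43 of 276 tRNA genes had an optimal summit in the promoter window (15.6%, 95% exact interval 11.5 to 20.4%) and on autosomes 8 of 336 (2.38%, 95% exact interval 1.03 to 4.64%; odds ratio 7.57, Fisher's exact test, two-sided, p = 3.9e-09). Among the highest peaks of each replicate the shares were 15.9% against 3.87% in replicate 1 (exact p = 4.4e-07) and 10.1% against 2.08% in replicate 2 (exact p = 2.9e-05). These p-values count neighbouring tRNA genes that share a summit as independent. Among snRNA genes, sls-2.4 (I, summit 4172187, signal 380.1), sls-2.2 (II, summit 5543656, signal 373.6) and sls-2.1 (II, summit 5844837, signal 365.7), which encode SL2 splice leader RNAs, had peaks ranked 24, 25 and 27. Of 18 SL2 genes 6 were bound, the others of these at ranks 392, 1221 and 1401.

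Of 8 comparisons of AGACGCAG and GAGAGAGA between classes of peaks, 5 differed. AGACGCAG was within 50 bp of 0 of 44 summits at ribosomal protein promoters (95% exact upper limit 8.04%) and of 103 of 884 at other promoters (11.7%, exact adjusted p = 0.0176). Outside promoters it was at 9 of 199 X summits (4.52%) and 66 of 535 autosomal ones (12.3%, exact adjusted p = 0.00387). Its share was 15.7% among the 415 highest and 8.92% among the 415 lowest peaks (exact adjusted p = 0.00827). Its shares in promoters and outside them did not differ detectably (11.1% against 10.2%, exact adjusted p = 0.660). GAGAGAGA was at 13.8% of summits outside promoters and 6.47% of those in them (exact adjusted p = 5.5e-06), and outside promoters at 5.53% of X and 16.8% of autosomal summits (exact adjusted p = 0.000135). It did not differ detectably between ribosomal protein and other promoters (0 of 44 against 6.79%, exact adjusted p = 0.143) or between the 415 highest and lowest peaks (8.92% against 8.19%, exact adjusted p = 0.804).

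X-linked peaks were frequent among the highest peaks outside promoters, 55 of 151 (36.4%). Background spread evenly over X DNA is argued against, since X held 4344 of 19795 relaxed peaks outside promoters below the optimal set (21.9%, Fisher's exact p = 6.6e-05). In the lower groups of the optimal set the X share was 22.5%, 21.3% and, among the 417 lowest, 29.8%. Stronger signal that any tagged protein gives at some X sites stays open, since no input or untagged sample was analysed here. Signal of a single replicate is argued against too, since the excess was present in replicate 1 (35.0% against 22.7%, exact p = 0.000475) and in replicate 2 (31.1% against 20.1%, exact p = 0.00241). A candidate explanation that stays open is that some of these are recruitment sites of the dosage compensation complex, which binds X. The core GCGCAGGG of the recruitment element lay within 100 bp of 10 of the 55 X summits (18.2%) and 1 of 96 autosomal ones (1.04%, exact p = 0.000182). Most X summits thus had no exact match to this core, and other forms of the element were not searched. The matches do not show whether the receptor itself is bound there.

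Ribosomal protein genes were bound far more often than other genes, 45 of 81 (55.6%). An NR4A element within 50 bp of the summits at these promoters is argued against, with 0 of 44 summits and an upper 95% exact limit of 8.04%. Wider windows were not run for these summits alone. Runs of neighbouring genes are argued against by shifting the bound state along the order of protein-coding genes, which keeps summits at promoters and gave 5.59 bound genes on average and at most 15, against 45 (one-sided permutation p = 0.00010, the smallest possible). Promoters that give weak peaks in any case are argued against as the whole cause by a comparison among genes with a relaxed peak in both replicates, 44 of 63 against 1119 of 4921 (69.8% against 22.7%, odds ratio 7.87, exact p = 4.3e-15). Signal that any tagged protein gives at very active promoters stays open, since no input or untagged sample was analysed here, and no biological explanation was tested.

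There were 8 stretches longer than 50 kb without a summit in any relaxed list. Repeated sequence is argued against for the longest, on chromosome V, and for that around nhr-6, where 94.7% and 99.3% of 31-mers occur once in the genome, against 91.6% elsewhere. The other stretches on V were mostly unique from 14850157 (85.96%) and from 15272142 (91.96%), and repeated from 2346294 (3.41%) and from 8811704 (3.27%), as were those on III from 7398251 (18.98%) and on IV from 1 (8.23%). Regions of seldom bound genes are argued against for the longest stretch, since of 261 bins of 100 kb outside it that held genes, but none of the lists bound more often and no optimal peak, 3 lacked a relaxed summit in both replicates (1.15%, upper 95% exact limit 3.32%), and the planned test with 7 genes could not reach the threshold (exact p = 0.0536). Masking of sequence that the transgene may bring in extra copies was not tested. It stays open for the stretch at nhr-6, since copy number was not measured. Lack of binding at nhr-6 was not tested either, and the cause of the mostly unique stretches on V stays open.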
